A study of Mus musculus with 16 samples.

How the data were processed

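RNA-seq was carried out on colonocytes, the epithelial cells that line the colon, from C57BL/6 mice fed for 3 weeks either a diet of corn oil with cellulose (9 libraries) or a diet of fish oil with pectin (7 libraries). Per the labels' protocols, total RNA was isolated with a micro-scale column kit and 200 ng entered a stranded poly(A) library preparation. The values used here are the raw read counts per gene symbol that the authors deposited, 1 column per library, with no normalisation. Per the submitters' processing notes, STAR 2.6.0a, HTSeq 0.11.1 and the mouse build GRCm38 were used. The strand setting and the annotation release of the counting are not given in the sources used here. Genes that overlap on opposite strands and genes with near-identical copies, such as Reg3b and Reg3g relatives, glutathione S-transferases and ribosomal proteins, therefore carry some uncertainty in how reads were divided. The labels number each library as a biological replicate but do not say whether each came from a separate mouse, so p-values measure the spread between these libraries.

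The table held 54392 gene symbols, and 0 per-sample columns were left unused. Library totals ran from 13996288 to 19512755 counts. The chi-square per degree of freedom between libraries of the same diet, over genes with at least 20 counts in a pair, ranged from 8.20 to 141 over 57 pairs, so no pair agreed within sampling noise. Symbols were matched to GENCODE M21 on GRCm38 for identifiers, coordinates and exon length, and 98.9% matched.

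The diets were compared with edgeR 4.0.16 (R 4.3.3) on the deposited counts, using its robust quasi-likelihood test, TMM scaling and the filterByExpr function, which kept 14321 genes holding 99.9% of all counts. Library names came in 2 forms: 10 began with GC (5 per diet) and 6 did not (4 corn oil/cellulose, 2 fish oil/pectin). What the forms stand for is not given in the sources used here. Since they may mark separate handling, the name form was a term of the model. Log2 fold changes and folds are fish oil/pectin against corn oil/cellulose, and are adjusted for the name form, whereas mean CPM are not. Standard errors were taken as the absolute log2 fold change over the square root of the F statistic, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Levels are CPM, counts scaled to a common library total with TMM factors.

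Before the data were examined, 22 gene lists and 19 cell type, region and sex marker lists were fixed, as were the main model, the other settings listed below as fixed and the rule for naming genes. Lists with at least 5 measured members (31 of 41) were tested with camera in limma 3.58.1 on voom values at a preset inter-gene correlation of 0.01, adjusted over the 31 lists. Beside this stand camera with an estimated correlation, the rotation test fry, and member counts both over all genes and adjusted over the list alone. Genes were named by 3 rules. The first took the 12 largest and 12 smallest log2 fold changes among genes past the threshold with an average of at least 1 log2 CPM, leaving out predicted genes, pseudogenes and immunoglobulin or T-cell receptor segments. Another took up to 4 members with the lowest p in each list, as examples. The last was a set of 21 genes fixed in advance. For the lists it describes, the text gives the first 1 to 3 of these examples in order of p. Some genes that these rules chose are not reported here and were not replaced.

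The settings fixed in advance were no term for the name form, a block for the replicate number, each name form alone, the libraries with the lower series of numbers in their names alone (4 corn oil/cellulose, 7 fish oil/pectin), leaving out each library, other scalings and filters, a non-epithelial marker score as a covariate, DESeq2 1.42.0, limma voom with quality weights, and other thresholds. After the data were examined, more were added: sex read from 4 Y-linked genes (over 100 counts taken as male) as a covariate and as a split, removal of each library's trend on exon length, alone or with GC content (loess, span 0.3), the diet effect within each name form and the difference between the forms, also with each library left out, a fit to the 14 libraries with Hoxd13 in the corn oil/cellulose range and another without the 2 libraries highest in Reg3g, and an exact permutation test of each list's mean log2 CPM. That permutation reassigned diets within name forms in all 3780 ways, was two-sided and was adjusted over the 31 lists. Fry and this permutation ask whether a list's members changed, whereas camera asks whether they changed more than other genes. It was added once the number of lists called by camera had been set against other groupings of the libraries. Permutation was also done within each name form, where 15 splits allow no p under 0.0667 without the GC prefix. Smaller camera p-values there rest on the preset correlation between genes. List medians were also compared with 10000 random lists matched on exon length and expression. The non-epithelial marker score was the mean log2 CPM of the measured T and NK, B and plasma, macrophage and dendritic, fibroblast, smooth muscle and endothelial markers, standardised across libraries.

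The steps were tested on simulated counts drawn from the means, spread and depths of these libraries. Of 200 genes changed in the comparison of the diets, the model recovered 83.6% of those changed by 1.5-fold, 94.0% by 2-fold and 100% by 4-fold, with 4 other genes called. With no change planted, 0 genes were called. The changed genes had an average of over 1 log2 CPM. Genes were drawn independently of each other, so the simulation does not test the calls of lists. These draws held no effect shared by genes within a library, such as a length trend. They therefore do not test false gene calls that such effects may cause. Of 100 genes with a planted 4-fold effect in GC-named libraries alone, 95% were recovered as differing between name forms.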

Results

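Transcriptomes of colonocytes were compared between mice fed corn oil with cellulose, a diet rich in n-6 fatty acids with a poorly fermented fibre, and mice fed fish oil with pectin, which supplies n-3 fatty acids and a fermentable fibre. The study concerns ferroptosis, an iron-dependent cell death driven by lipid peroxidation. The 9 corn oil/cellulose libraries held 13996288 to 19331984 counts and the 7 fish oil/pectin libraries 16212831 to 19512755. Of the corn oil/cellulose libraries 5 had names beginning with GC, as had 5 of the fish oil/pectin libraries; 4 and 2 did not.

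The diets differed over much of the colonocyte transcriptome, mostly by small amounts. Of 14321 genes tested, 5979 (41.7%) passed the threshold, 3103 of them higher and 2876 lower with fish oil/pectin, with a median absolute log2 fold change of 0.37. Only 47 of these rose by a doubling or more and 251 fell by a halving or more. Genes of DNA replication, mitosis, cholesterol synthesis, glutathione metabolism and oxidative phosphorylation lay higher with fish oil/pectin, and circadian clock genes lay lower. Oxidative phosphorylation genes averaged 0.47 in GC-named and 0.07 in the other libraries, and glutathione genes 0.45 and 0.20. T cell markers lay lower in GC-named libraries (-1.36) and not in the others (0.01). By camera 10 of 31 lists passed, and 0 with an estimated correlation, where 1 had an unadjusted p under 0.05. By exact permutation within name forms 13 passed: all of the 10 but PPAR targets, with fatty acid synthesis, ferroptosis suppressors, short-chain fatty acid genes and macrophage markers added. The permutation does not compare a list with other genes. Scaled by total counts alone, 6026 genes passed, 2247 higher and 3779 lower, so 37.3% of calls were higher against 51.9% with TMM scaling. Fitted alone, the GC-named libraries gave 5663 genes and the others 900. With an effect for each name form in a joint edgeR fit, 0 genes passed in the others, where 2385 had an unadjusted p under 0.05.

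**Figure D1:**
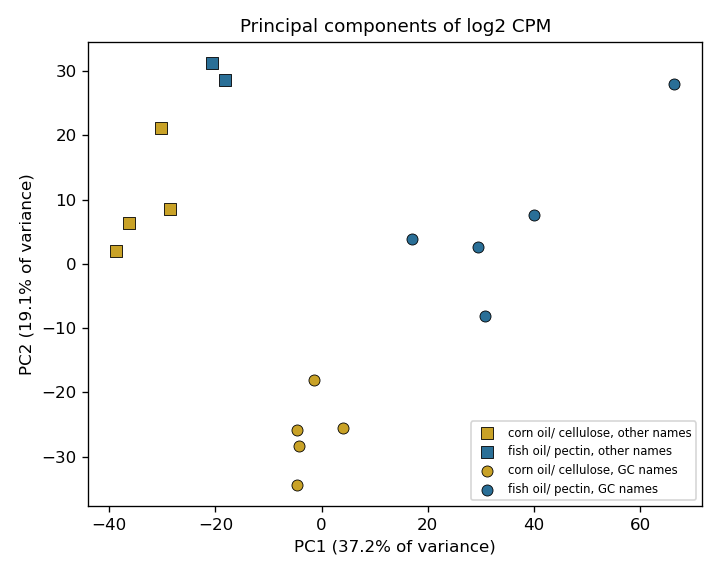
Scores of the 16 libraries on the first principal components of log2 CPM, with PC1 (37.2% of variance) on the x axis and PC2 (19.1%) on the y axis; colour gives the diet and shape the library name form, 1 point per library. Libraries without the GC prefix had PC1 scores of -38.7 to -18.3, GC-named corn oil/cellulose libraries -4.59 to 4.04 and GC-named fish oil/pectin libraries 17.1 to 66.4.

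Among the genes with the largest increases were several of the antimicrobial epithelial response. Reg3g (ENSMUSG00000030017.2, chromosome 6, 78466269 to 78468872, minus strand, GRCm38) and Reg3b (chromosome 6, 78370657 to 78373466, plus strand), which encode secreted C-type lectins that act on bacteria, had log2 fold changes of 3.87 ± 1.10 (SE, adjusted p = 0.0131) and 3.62 ± 1.16 (adjusted p = 0.0241). Reg3g averaged 29.8 ± 31.4 CPM (SD, n = 9) with corn oil/cellulose and 692 ± 1070 CPM (SD, n = 7) with fish oil/pectin. Lrg1, a secreted leucine-rich glycoprotein gene (chromosome 17, 56119678 to 56122001), averaged 0.292 ± 0.173 and 5.27 ± 6.71 CPM, with a fitted log2 fold change of 3.91 ± 0.85. Duoxa2, the maturation factor of the hydrogen peroxide-producing oxidase Duox2, rose by 1.60 ± 0.30, and Retnlb, a goblet cell antimicrobial protein gene, by 1.41 ± 0.37. Without fish oil/pectin library 7, which had the highest Reg3g, the log2 fold changes were 3.13 for Reg3g, 2.65 for Reg3b and 3.40 for Lrg1, and all 3 still passed. Reg3g was at 2746 CPM in that library, 1619 CPM in library 6 and 49.2 to 152 CPM in the other fish oil/pectin libraries, against up to 92.8 CPM with corn oil/cellulose. Without libraries 6 and 7 together Lrg1 still passed (2.28, adjusted p = 0.00385), and Reg3g (1.70, adjusted p = 0.0779) and Reg3b (1.47, adjusted p = 0.153) did not. In GC-named and other libraries Reg3g was at 4.63 ± 1.28 and 2.01 ± 1.51 and Reg3b at 4.42 ± 1.33 and 1.57 ± 1.54. In the others fitted alone Reg3g did not pass (adjusted p = 0.254), as under 7 settings in all. The list of antimicrobial and microbiota-responsive genes rose as a group, with 9 of 22 measured members higher and 1 lower (9 and 1 adjusted over the list alone; camera adjusted p = 0.00919, and adjusted p = 0.514 with an estimated correlation). Nox1, a superoxide-producing oxidase, rose by 0.74, and Tlr5, the flagellin receptor, was the member that fell, by 0.84 on the log2 scale. The list averaged 0.94 in GC-named (adjusted p = 0.0193) and 0.47 in the other libraries (adjusted p = 0.111). Its call was lost in the latter alone (0.48, adjusted p = 0.0536) and with a non-epithelial marker score in the model (0.77, adjusted p = 0.0703).

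Other genes also had large increases. Cbr3, a carbonyl reductase gene (ENSMUSG00000022947.8, chromosome 16, 93683215 to 93690990), averaged 12.8 ± 3.84 CPM (SD, n = 9) with corn oil/cellulose and 32.8 ± 3.99 CPM (SD, n = 7) with fish oil/pectin. In the model, which adjusts for the name form, it rose 2.70-fold (log2 fold change 1.43 ± 0.14, edgeR adjusted p = 9.19e-05). Fabp6, the ileal bile acid-binding protein gene, had a log2 fold change of 2.05 ± 0.48, or 1.46 without fish oil/pectin library 7. H2-Q10, a class I histocompatibility gene, rose by 1.73 ± 0.25, and Lrp8, a lipoprotein receptor gene, by 1.44 ± 0.33. Clca4b rose by 2.01 ± 0.54, a call lost without fish oil/pectin library 2 (1.35, adjusted p = 0.0619). Mfsd2a, a transporter of lysophospholipids that carry n-3 fatty acids, had a log2 fold change of 1.65 ± 0.58 (adjusted p = 0.0311). Its call was lost without any of corn oil/cellulose libraries 1, 4, 5, 6 or 9 or fish oil/pectin libraries 2 or 7, with values from 1.15 to 1.57.

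Among the genes with the largest decreases, Scnn1g, the gamma subunit of the epithelial sodium channel (ENSMUSG00000000216.8, chromosome 7, 121734479 to 121768475), fell from 4.51 ± 3.55 CPM (SD, n = 9) to 0.713 ± 0.491 CPM (SD, n = 7), with a fitted log2 fold change of -2.74 ± 0.49 (edgeR adjusted p = 0.000795). Itgb8, an integrin subunit gene, changed by -2.06 ± 0.34, the long noncoding RNA Miat by -1.67 ± 0.21 and Klk15, a kallikrein-related peptidase gene, by -1.64 ± 0.43. Over all libraries Rgs1, Fmnl1, Rasal3, Dock10, Dock2, Itgb2 and Msn had log2 fold changes of -1.90, -1.81, -1.63, -1.53, -1.51, -1.44 and -1.41. These 7 genes, in that order, were at -2.12, -2.25, -2.14, -2.16, -1.93, -2.07 and -2.17 in GC-named libraries and at -0.44, -0.55, -0.33, -0.29, -0.33, -0.01 and 0.18 in the others, where none passed in the joint fit, as was so for the T and NK cell markers below. Of these differences between name forms that of Rgs1 did not pass (adjusted p = 0.0724), and only that of Msn passed whichever library was left out. Itgb2 encodes the shared beta chain of leukocyte integrins.

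**Figure D2:**
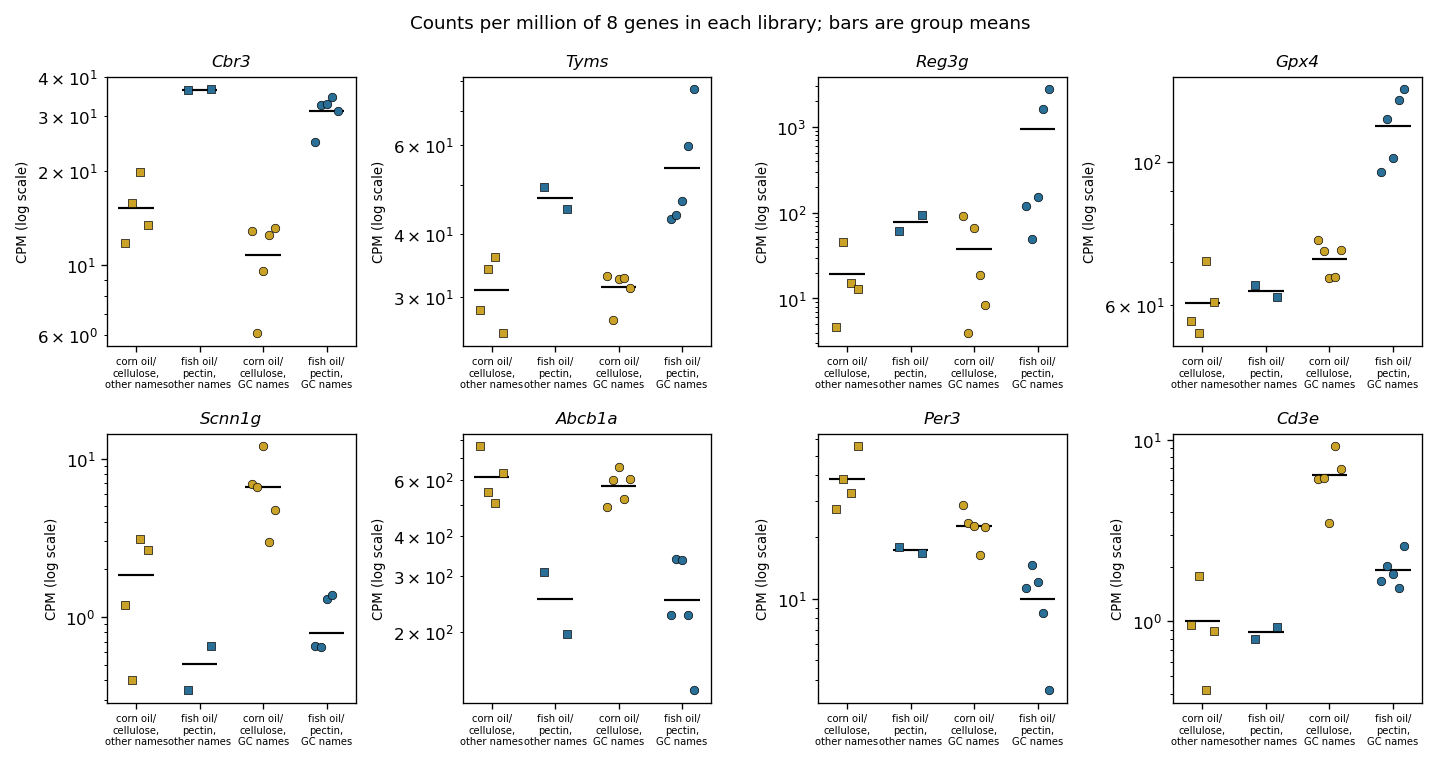
CPM on a log scale of 8 genes, 1 point per library, by diet and library name form; bars are group means on the linear scale, and fish oil/pectin library 7, with 0 CPM of Scnn1g, is counted in that mean but has no point on the log axis. Cbr3 averaged 10.8 and 31.3 CPM in GC-named corn oil/cellulose and fish oil/pectin libraries and 15.3 and 36.5 CPM in the others, whereas Gpx4 averaged 70.8 and 114 CPM in the former and 60.3 and 63.0 CPM in the latter.

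The question of ferroptosis was addressed with genes that restrain it, genes that promote it and genes of iron handling. Gpx4, the glutathione peroxidase that reduces lipid hydroperoxides (ENSMUSG00000075706.10, chromosome 10, 80047166 to 80056439), averaged 66.1 ± 7.62 CPM (SD, n = 9) with corn oil/cellulose and 99.4 ± 27.5 CPM (SD, n = 7) with fish oil/pectin. Adjusted for the name form it rose 1.39-fold (log2 fold change 0.48 ± 0.10, edgeR adjusted p = 0.00142). The increase differed between name forms: it was 0.69 ± 0.09 in GC-named and 0.06 ± 0.12 in the other libraries, a difference of 0.62 (adjusted p = 0.0241). That difference did not pass without fish oil/pectin library 1 (0.65, adjusted p = 0.0658) or 2 (0.59, adjusted p = 0.178) or corn oil/cellulose library 3 (0.54, adjusted p = 0.0524). Its call was lost in the other libraries alone (0.07, adjusted p = 0.705), in male libraries (0.17, adjusted p = 0.214) and with a non-epithelial marker score in the model (0.34, adjusted p = 0.0576). Of the genes that put polyunsaturated fatty acids into membranes, Acsl4 rose by 0.30 ± 0.10 (adjusted p = 0.0205), with 0.29 and 0.33 in the name forms, and Lpcat3 by 0.29 ± 0.05 (adjusted p = 0.000542), with 0.30 and 0.26. The call of Acsl4 was lost under 9 settings, among them either name form alone (adjusted p = 0.158 and 0.0785) and scaling by total counts (0.23, adjusted p = 0.0668). Tfrc, the transferrin receptor gene, had a log2 fold change of 0.44 ± 0.15 (adjusted p = 0.0256), lost without corn oil/cellulose library 6 or 9 or fish oil/pectin library 2 or 7 (0.30 to 0.40). Slc7a11, the cystine transporter gene, did not pass, at 0.02 ± 0.19 (adjusted p = 0.949), nor did Hmox1 (-0.10), Aifm2 (-0.04) or, over all libraries, Fth1 (0.02). Fth1 was at 0.22 in GC-named (adjusted p = 0.0482) and -0.37 in the other libraries (adjusted p = 0.201), a difference of 0.585 (adjusted p = 0.0286) that did not pass without fish oil/pectin library 1 (0.62) or 2 (0.55) or corn oil/cellulose library 3 (0.53).

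Neither ferroptosis list passed by camera. Of 23 suppressors, 9 rose and 4 fell, the same over all genes and adjusted over the list alone (camera adjusted p = 0.397; adjusted p = 0.533 with an estimated correlation). Gsr, glutathione reductase, rose by 0.39 and Sepsecs, of selenocysteine synthesis, fell by 0.33. Of 23 drivers, 9 rose and 2 fell (adjusted p = 0.154). Nox1 rose by 0.74 and Pebp1, a lipoxygenase partner, by 0.45. Of 19 iron handling genes, 3 rose and 4 fell (adjusted p = 0.990), with Ftl1 at 0.34, Pcbp1 at 0.24 and Ireb2 at -0.25. The calls were lost under 6 settings for Ftl1 and 7 each for Pcbp1 and Ireb2, among them removal of the transcript length trend (0.10, 0.04 and -0.08), and Ftl1 was at -0.04 in the libraries without the GC prefix alone. By the exact permutation test within name forms the suppressor list differed (adjusted p = 0.0321) and the driver list did not (adjusted p = 0.0838). By fry both lists passed (adjusted p = 0.00656 and 0.00361). The suppressor list had the smaller mean log2 fold change, 0.07 against 0.14 for drivers. Among random lists of matched length and expression their medians stood at percentiles 69.5 and 98.7, so the tests do not set the 2 lists apart.

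On average genes of the cell cycle lay higher with fish oil/pectin in both name forms. In the joint fit 0 members of these lists passed in the libraries without the GC prefix. All 22 S phase genes were higher, over all genes and adjusted over the list alone (camera adjusted p = 4.4e-08, or adjusted p = 0.514 with an estimated correlation). Their mean log2 fold change was 0.54 in GC-named (camera adjusted p = 0.00172) and 0.85 in the other libraries (adjusted p = 9.5e-18). Exact permutation p was 0.0397 and 0.0667, the latter the lowest that 15 splits allow. Camera took a correlation of 0.01 between genes, whereas the estimate for this list was 0.87. Tyms, thymidylate synthase, rose by 0.72 ± 0.12 and Gins2, of the replicative helicase, by 0.82 ± 0.14. Of 24 G2 and M phase genes 18 rose (21 adjusted over the list alone) and 0 fell (camera adjusted p = 8.3e-07; adjusted p = 0.533 with an estimated correlation). Cdk1 rose by 0.79 ± 0.15 and Ube2c by 0.77 ± 0.15. The list means were 0.47 (camera adjusted p = 0.0023) and 0.53 (adjusted p = 1.1e-10) in the name forms, with exact permutation p of 0.0556 and 0.0667. Fish oil/pectin libraries 6 and 7 were highest among the GC-named, with mean log2 CPM of 5.58 and 5.73 for this list and 5.62 and 6.03 for S phase. Libraries 3, 4 and 5 stood at 4.97, 4.95 and 5.17 and at 5.20, 4.82 and 5.15. GC-named corn oil/cellulose libraries stood at 4.46 to 5.20 and at 4.65 to 5.13. Mki67, a marker of cycling cells, did not pass, at 0.36 ± 0.15 (adjusted p = 0.0599). The stem cell list did not pass, with 2 of 19 members higher and 3 lower (camera adjusted p = 0.807). Its mean was -0.14 in GC-named (adjusted p = 0.160) and 0.18 in the other libraries (adjusted p = 0.0293), with exact permutation p of 0.119 and 0.2. Sox9 was at -0.24, Slc12a2 at -0.39 and Lgr5 at -0.18 ± 0.12 (adjusted p = 0.267).

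Cholesterol synthesis rose as a group, with 15 of 25 genes higher and 0 lower (16 and 0 adjusted over the list alone; camera adjusted p = 1.6e-05, adjusted p = 0.514 with an estimated correlation). The means were 0.40 in GC-named (adjusted p = 0.00729) and 0.49 in the other libraries (adjusted p = 1.9e-09), with exact permutation p of 0.0397 and 0.0667. Nsdhl rose by 0.52 ± 0.08 and Mvd by 0.84 ± 0.15. The call was lost in female libraries (0.31, adjusted p = 0.0740). In fatty acid synthesis and desaturation 6 of 16 genes rose and 1 fell (camera adjusted p = 0.0692, exact permutation adjusted p = 0.00547). The mean was 0.18 in GC-named (camera adjusted p = 0.386) and 0.30 in the other libraries (adjusted p = 0.00108). Fads1, the delta-5 desaturase (chromosome 19, 10182888 to 10196877), rose 2.17-fold, Elovl5, an elongase of polyunsaturated fatty acids, by 0.31 and Scd1, the delta-9 desaturase, by 0.42 ± 0.11 on the log2 scale, whereas Fads2 (-0.10), Fasn (0.06) and Srebf1 (0.20, adjusted p = 0.094) did not pass. The call of Scd1 was lost under 7 settings, with values from 0.33 to 0.54, among them the GC-named libraries alone (0.33) and the others alone (0.54).

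NRF2 targets and glutathione genes rose, with 23 of 31 higher and 1 lower (24 and 1 adjusted over the list alone; camera adjusted p = 1.3e-07, adjusted p = 0.514 with an estimated correlation). The means were 0.45 in GC-named (adjusted p = 7.2e-07) and 0.20 in the other libraries (adjusted p = 8.0e-05), with exact permutation p of 0.00794 and 0.133. Besides Cbr3, the glutathione S-transferase gene Gsta3 rose 2.47-fold, and Gstt1 rose by 0.58 ± 0.09 on the log2 scale. Of the nuclear genes of oxidative phosphorylation 37 of 40 rose (37 adjusted over the list alone; camera adjusted p = 6.8e-13, adjusted p = 0.514 with an estimated correlation). Much of this was shared by genes of like length and expression: the list's median was 0.35, against 0.28 for random lists matched on both (percentile 93.4). With the transcript length trend removed the list mean was 0.17, against 0.34 before, and the list still passed. Cyc1 rose by 0.36 ± 0.06 and Uqcrq by 0.63 ± 0.11. Their mean was 0.47 in GC-named and 0.07 in the other libraries, and the forms differed by camera (adjusted p = 2.0e-17) but not with an estimated correlation (adjusted p = 0.643). In the unfolded protein and integrated stress response 11 of 23 genes rose (12 adjusted over the list alone; camera adjusted p = 0.0122, adjusted p = 0.767 with an estimated correlation). Calr rose by 0.57 and Sdf2l1 by 0.99. The list mean was 0.47 in GC-named (adjusted p = 0.0557; exact permutation p = 0.167) and 0.34 in the other libraries (adjusted p = 0.0218). Fish oil/pectin libraries 7 and 6 stood apart, with mean log2 CPM of 7.15 and 6.60, while the other GC-named fish oil/pectin libraries, at 5.98 to 6.24, lay within the 5.89 to 6.24 of GC-named corn oil/cellulose. Without library 7 the list passed with a mean of 0.27, against 0.42 with it. The call was lost in female libraries (0.49, adjusted p = 0.0578) and with the transcript length trend removed (0.32, adjusted p = 0.0504).

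Fatty acid oxidation moved less. Of 38 PPAR target and fatty acid oxidation genes 14 rose and 2 fell (14 and 2 adjusted over the list alone; camera adjusted p = 0.0421, adjusted p = 0.771 with an estimated correlation). The mean was 0.19 in GC-named (adjusted p = 0.0062) and -0.02 in the other libraries (adjusted p = 0.915). The call was lost without corn oil/cellulose library 2, 3, 7 or 8 or fish oil/pectin library 3, 4 or 5 (0.09 to 0.12) and with the length trend removed (0.06, adjusted p = 0.149). Etfa and Etfb, which pass electrons from fatty acid oxidation, rose by 0.33 and 0.74. Cpt1a, the gate of mitochondrial fatty acid import, had a log2 fold change of -0.31 ± 0.11 (adjusted p = 0.0312). This was lost without corn oil/cellulose library 4, 6 or 9 or fish oil/pectin library 1, 6 or 7 (-0.29 to -0.24). Angptl4 (0.05) and Pdk4 (-0.10) did not pass, and Fabp1 was too low to be tested. In short-chain fatty acid transport and use 6 of 17 genes rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.249), with Bdh1 at 0.36. The transporter genes Slc5a8 (-0.16) and Slc16a1 (-0.05) did not pass.

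Clock genes fell, with 9 of 16 lower and 1 higher (9 and 1 adjusted over the list alone; camera adjusted p = 0.0155, adjusted p = 0.514 with an estimated correlation). The means were -0.44 in GC-named (adjusted p = 0.0240) and -0.42 in the other libraries, where the list did not pass (adjusted p = 0.152). Per3 (chromosome 4, 151003652 to 151044665) fell from 29.8 ± 11.6 CPM (SD, n = 9) to 12.1 ± 4.98 CPM (SD, n = 7), and Ciart fell by 1.28 ± 0.22 on the log2 scale. Abcb1a, a xenobiotic efflux pump gene (chromosome 5, 8660077 to 8748575), fell from 591 ± 86.1 to 252 ± 78.6 CPM. Its list, xenobiotic metabolism, did not pass, with 2 of 27 genes higher and 6 lower (2 and 4 adjusted over the list alone; adjusted p = 0.397), and Aldh1a7 at 0.51. The list mean was -0.04 in GC-named (adjusted p = 0.864) and -0.40 in the other libraries (adjusted p = 6.1e-05).

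T and NK cell markers were lower with fish oil/pectin in GC-named libraries. Over all libraries 10 of 13 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 4.1e-05; adjusted p = 0.514 with an estimated correlation). Cd3e (chromosome 9, 44998740 to 45009627) was at -1.36 ± 0.28 and Cd3d at -1.33 ± 0.25. The mean log2 fold change was -1.36 in GC-named (adjusted p = 1.8e-05) and 0.01 in the other libraries (adjusted p = 0.918), a difference of -1.37 (camera adjusted p = 0.000106; adjusted p = 0.643 with an estimated correlation). Cd3e averaged 6.36 and 1.92 CPM in GC-named corn oil/cellulose and fish oil/pectin libraries and 1.01 and 0.871 CPM in the others. The call of the T and NK list was lost without the name form term (-0.90, adjusted p = 0.160) and with a non-epithelial marker score in the model (-0.06, adjusted p = 0.611). That score includes the T and NK markers themselves, so the latter loss was largely fixed in advance and carries no conclusion. Of the macrophage and dendritic cell markers 4 of 9 fell, among them Lyz2 by 0.90 and Fcer1g by 0.83, and 1 rose (adjusted p = 0.140).

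The remaining lists did not pass over all libraries. Interferon-stimulated genes had 5 of 27 higher and 0 lower (0 and 0 adjusted over the list alone; adjusted p = 0.271). In the libraries without the GC prefix their mean was 0.89 (adjusted p = 3.5e-05), and that of MHC class II genes 1.43 (adjusted p = 0.00325). Both values rest on fish oil/pectin library 2, with mean log2 CPM of 3.77 for interferon-stimulated and 4.398 for MHC class II genes, whereas library 1 stood at 2.34 and 2.42 and the corn oil/cellulose libraries averaged 2.40 and 2.36. Immediate early and heat shock genes had 1 of 20 higher and 8 lower (1 and 9 adjusted over the list alone; adjusted p = 0.0527; Egr2 at -1.18 and Dusp1 at -0.55), with means of -0.35 in GC-named (adjusted p = 0.0193) and -0.02 in the other libraries (adjusted p = 0.915). Mean log2 CPM of this list was 6.93 and 6.56 in GC-named corn oil/cellulose and fish oil/pectin libraries, and 4.64 and 4.69 in the others. Its level thus differed more between name forms than between diets, for a reason that was not tested. P53 and apoptosis genes had 3 of 24 higher and 4 lower (2 and 4 adjusted over the list alone), MHC class II genes 0 of 8 in either direction, and cytokine and eicosanoid genes 1 of 13 higher and 3 lower (0 and 1 adjusted over the list alone), with a median of 0.00 and a mean of -0.10. Of epithelial markers, the absorptive list had 2 of 18 higher and 2 lower (0 and 0 adjusted over the list alone). Its mean was 0.19 in GC-named (adjusted p = 0.354) and -0.28 in the other libraries (adjusted p = 0.00739). Goblet markers had 3 of 13 higher and 2 lower, deep crypt secretory 0 of 6 higher and 1 lower with a median of 0.06 and a mean of -0.03, enteroendocrine 1 of 15 higher and 2 lower (0 and 0 adjusted over the list alone), and tuft 0 of 11 in either direction. The proximal region list had 1 of 9 higher and 1 lower (0 and 1 adjusted over the list alone) and the distal list 0 of 9; sex-linked genes had 0 of 5, with a mean of -0.60 although camera placed them upward. Lists with fewer than 5 measured members were not tested as groups: B and plasma cell (0 higher and 2 lower of 4; 1 and 2 adjusted over the list alone), glia and neuron (0 and 2 of 3), smooth muscle (2 and 1 of 3), fibroblast (1 and 0 of 1), endothelial (0 of 3), squamous (0 of 4), adipocyte, erythrocyte and pancreas (0 of 1 each). None of the 13 mitochondrially encoded genes was measured.

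**Figure D3:**
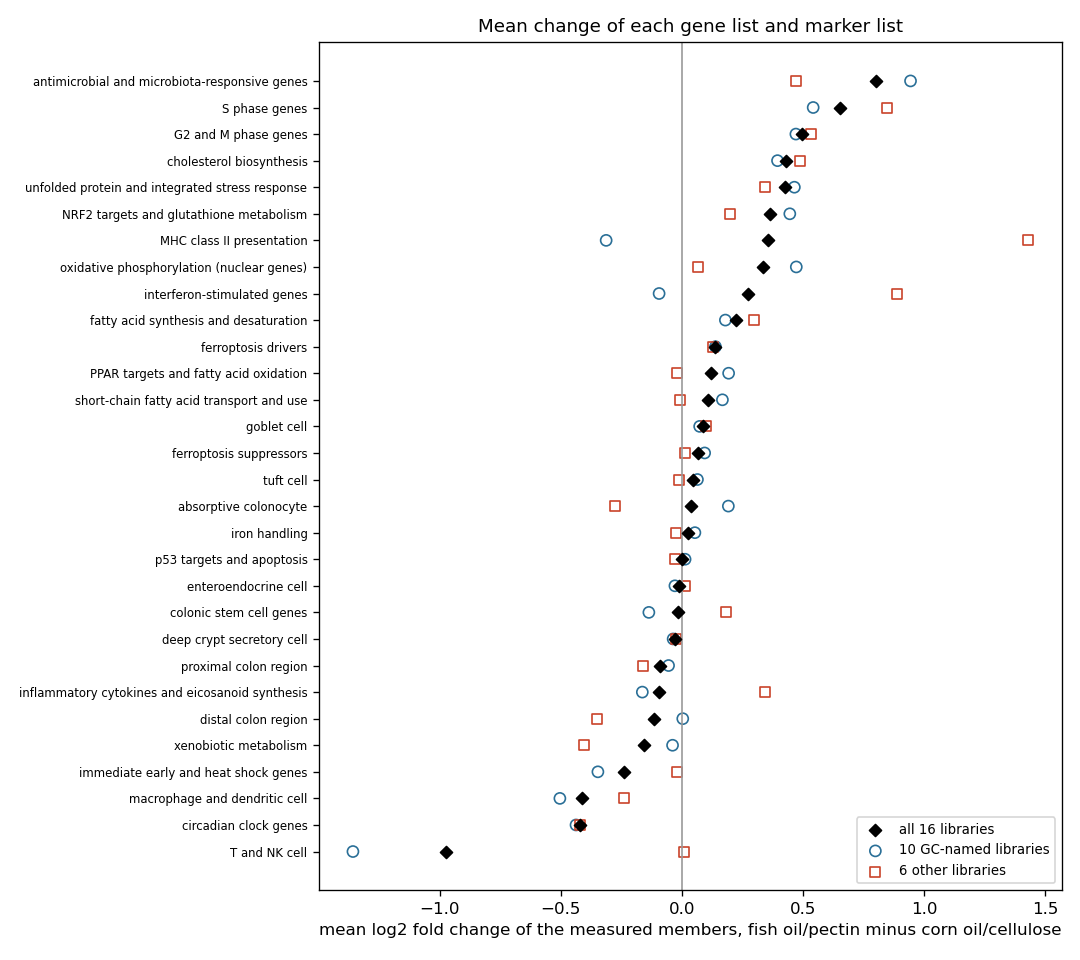
Mean log2 fold change (x axis, fish oil/pectin minus corn oil/cellulose) of the measured members of each list (y axis), over all 16 libraries (diamonds), the 10 GC-named libraries (circles) and the 6 others (squares). S phase, G2 and M phase and cholesterol genes lay above 0 and clock genes below 0 in both name forms, whereas T and NK cell markers lay at -1.36 and 0.01.

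The diet effect was compared between name forms. It differed for 1204 genes and for 11 of the 31 lists (camera; 0 lists with an estimated correlation, adjusted or unadjusted). The number of genes was 6 without fish oil/pectin library 2 and 261 without library 1, the 2 fish oil/pectin libraries without the GC prefix. Of the 5979 genes called over all libraries, 5360 (89.6%) had the same sign in both forms, but a call in a fit to both forms favours such agreement. Across all tested genes, which are not independent replicates, the effects correlated at r = 0.359. The name form itself went with 5799 genes.

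The response also followed transcript length. Across genes the diet log2 fold change correlated with exon length at a Spearman rho of -0.42 (-0.48 in GC-named and -0.12 in the other libraries). Among genes with an exon length up to 2436 bases 1275 were higher and 180 lower, and among those of at least 6470 bases 253 were higher and 1618 lower. Per library, the correlation of log2 CPM deviations with exon length averaged 0.156 ± 0.065 (SD, n = 5) in GC-named corn oil/cellulose and -0.424 ± 0.057 (SD, n = 5) in GC-named fish oil/pectin libraries (exact two-sided permutation p = 0.00794). In the others it averaged 0.354 ± 0.046 (SD, n = 4) against 0.223 and 0.281 (exact permutation p = 0.133, where 15 splits allow no p under 0.0667). With the trend removed 4614 genes passed. The median of the oxidative phosphorylation list stood at percentile 93.4 among random lists of matched length and expression and the PPAR list at 81.7, whereas S phase, G2 and M phase, cholesterol and unfolded protein lists stood at 100. Lists that did not pass stood at the ends as well, interferon-stimulated genes at 100, MHC class II genes at 99.9, xenobiotic metabolism and enteroendocrine markers at 0.01 and immediate early genes at 0, so an extreme percentile alone does not mark a list as changed.

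**Figure D4:**
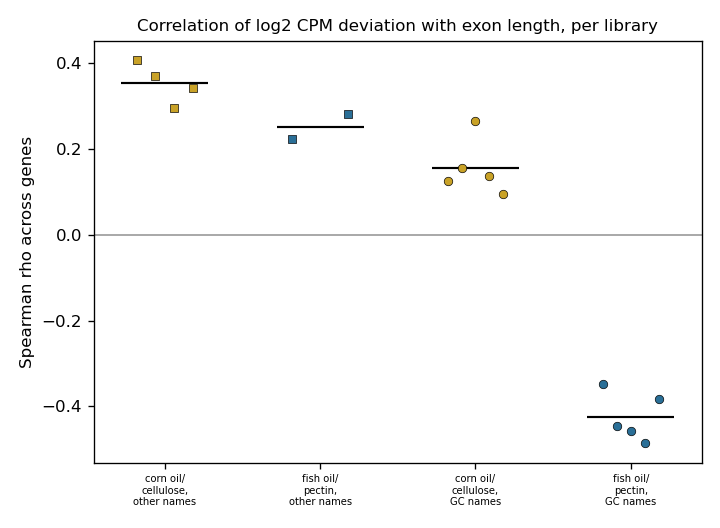
Spearman correlation across genes (y axis) between each library's log2 CPM deviation and exon length, 1 point per library, by diet and library name form (x axis); bars are group means. GC-named fish oil/pectin libraries averaged -0.424 and all other groups lay above 0.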

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

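Apart from the comparisons with other groupings of the libraries, the tests of explanations in this part were chosen after the results they concern were seen, as were the comparisons between name forms.

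The pattern of genes that differed between the diets was set against 100 groupings of the 16 libraries into 9 and 7. Only 1 of the 100, the real one, called as many genes, 5979, and the highest other called 4. Chance is thus argued against for the number of genes, at 1 in 100, the smallest share these groupings allow. They were not drawn within name forms, and the diet difference stayed in the spread of the others, which can lower their calls. Chance cannot be excluded for the number of lists called by camera: 64 of the 100 groupings called at least the 10 lists of the real one, and the highest other called 17. Handling marked by the name form is argued against as the whole cause by the 5663 genes that passed within the GC-named libraries. The length trend itself is argued against as the whole cause by the 61.5% of called genes called again in the same direction once it was removed. Removal takes out only the part linked to length, so other effects of whatever caused the trend stay open. Per library the trend ran from 0.0941 to 0.265 in GC-named corn oil/cellulose and from -0.486 to -0.348 in GC-named fish oil/pectin. A diet effect remains open as a hypothesis, while the number of called lists is no evidence for it.

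The fall of T and NK cell markers was the second pattern, with a difference of -1.37 between name forms (camera adjusted p = 0.643 with an estimated correlation). A length trend is argued against, since the list mean over all libraries was -1.15 with the trend removed and -0.97 before. In GC-named libraries T and NK markers stood at -1.36 relative to 10 stromal markers (SE 0.244, exact permutation p = 0.00794). Of these 10, Fbln1 was at 1.18, Tpm2 at 1.24 and Mylk at -0.49. T and NK markers thus fell relative to this set. A loss of non-epithelial cells of every type stays open, because only 1 of 11 fibroblast, 3 of 11 smooth muscle and 3 of 10 endothelial markers were measured. Whether the markers left follow stromal cells in these libraries was not tested. A loss shared by leukocytes stays open, as T and NK minus macrophage and dendritic markers gave -0.769 (SE 0.402; exact permutation p = 0.0952). Fewer immune cells in the mucosa and carry-over of immune cells that varied with handling cannot be told apart, because the list stood at 0.0107 in the other libraries, where its mean log2 CPM was 0.468 and 0.532 in the diets against 2.42 in GC-named corn oil/cellulose libraries. Counts of T cells in tissue sections, not analysed here, would be needed to decide.

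The rise of Reg3g, Reg3b and Lrg1 was the third, and a single library is argued against as the sole source, since Reg3g was 3.13 (SE 0.941) without its highest library; that 2 libraries carried Reg3g stays open, as without libraries 7 (2746 CPM) and 6 (1619 CPM) it was at 1.70 (SE 0.676, adjusted p = 0.0779), while Lrg1, at 2.28, still passed. RNA of the ileum stays open: of 20 ileum markers, chosen after the rise was seen, 12 reached 1 CPM, with a median difference of 0.134 in GC-named libraries, 6 higher and 6 lower. Fabp6 was higher by 2.12, whereas Sis (-1.17) and Slc10a2 (-0.14) were lower and Apoa1 (0.541 CPM), Defa24 (0.197 CPM), Fgf15 (0.158 CPM), Apoc3 (0.104 CPM), Apoa4 (0.0309 CPM) and Defa22 (0 CPM) stayed near 0 with fish oil/pectin, which goes against ileum RNA without a measured share to exclude it. The colon region sampled, as marked by Hoxd13, is argued against as the whole source: among the 14 libraries with Hoxd13 in the corn oil/cellulose range, library 6 included, the log2 fold changes were 3.37 (SE 1.03) for Reg3g, 2.90 (SE 1.03) for Reg3b and 3.77 (SE 0.744) for Lrg1, and all passed. It stays open for library 7, with 0.631 CPM of Hoxd13, and differences in the microbiota were not tested.

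A single library stood apart from the rest of its diet in 12 of 152 groups of values, where chance gives about 7.60, and 5 of the 12 were fish oil/pectin library 7. That library was low in Itgb8 (0.230 CPM), Klk15 (0.0574 CPM), Fads2 (152 CPM), clock genes (mean log2 CPM 4.14) and distal colon genes (2.75). Fish oil/pectin library 3 was low in Cbr3 (24.9 CPM), library 1 in Fmnl1 (0.575 CPM) and library 5 in Itgb2 (0.377 CPM), and library 2 was high in MHC class II genes (mean log2 CPM 4.398). Corn oil/cellulose library 2 was low in Klk15 (3.74 CPM), library 9 in Acsl4 (9.13 CPM), and library 3 was high in iron handling genes (mean log2 CPM 6.36).

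The diet effect differed between name forms, as GC-named minus others, for 1204 genes. By a test of the difference itself (edgeR interaction, adjusted p of 0.00396 to 0.0358), among 41 named genes it differed for Fmnl1 (-1.70), Rasal3 (-1.81), Dock10 (-1.87), Dock2 (-1.60), Itgb2 (-2.07), Msn (-2.35), Gpx4 (0.62) and Fth1 (0.585). Among lists it differed by camera, though for 0 with an estimated correlation, for PPAR targets (0.21), NRF2 targets (0.25), xenobiotic metabolism (0.36), oxidative phosphorylation (0.41), stem cell genes (-0.32), S phase genes (-0.31), interferon-stimulated genes (-0.98), MHC class II (-1.74), immediate early genes (-0.33), absorptive markers (0.47) and T and NK markers (-1.37).

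Many of these differences depended on single libraries. The number of genes ran from 6 (without fish oil/pectin library 2) to 1763 (without library 3). Without library 2 the differences were 0.0094 for interferon-stimulated genes (adjusted p = 0.687) and -0.36 for MHC class II (adjusted p = 0.549), so these 2 rest on that library. Fmnl1 (-1.21) and Dock10 (-1.40) also lost the call without library 2 alone. The call was lost in 8 of the 16 omissions for Rasal3, in 7 for S phase genes, and in 3 each for Dock2, Itgb2, Gpx4, Fth1 and immediate early genes. It was lost in 0 for Msn, PPAR targets, NRF2 targets, xenobiotic metabolism, oxidative phosphorylation, stem cell genes, absorptive markers and T and NK markers. Without library 1 or 2 the fish oil/pectin group of that name form is 1 library, and its spread was taken from the other groups.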

How the results depend on the processing

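The settings for sex, transcript length and permutation were chosen after the data were seen; the others were planned. Diet genes numbered 5979, with 3103 higher and 2876 lower. Counts moved by over 1.5 times with replicate block and name form over 14 libraries (3501; 1895 higher, 1606 lower), in libraries without the GC prefix (900; 614 and 286), in the libraries with the lower series of numbers (2250; 1194 and 1056), in male libraries (1458; 893 and 565) and with a non-epithelial marker score (3360; 2036 and 1324). The cause was not tested. All 7 fish oil/pectin libraries were of the lower series of numbers, so the main model does not separate an effect of the series from diet. A required doubling or halving, stricter by construction, left 298 (47 and 251). Under the other settings, leave-one-out aside, the count lay within 1.5 times, from 4353 in female libraries to 7208 at an adjusted p under 0.1. Leaving out single libraries gave 5078 to 6065 genes (2660 to 3146 higher, 2416 to 2936 lower) and 9 to 12 gene lists. Of 10 gene lists called, 0 held with an estimated correlation (camera, where 1 list had an unadjusted p under 0.05), 13 passed with fry and 13 by exact permutation. Fry and the permutation do not compare a list with other genes, of which 41.7% of those tested passed. Their counts therefore do not show that these lists changed more than the rest.

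The replicate numbers did not pair the libraries: 4 of 7 same-numbered pairs had deviations correlated above 0.1 (range -0.0678 to 0.475) and 1 of 7 correlated best with its own number. These deviations were from diet means, so libraries of the same name form can correlate through it. Taken from means of diet and name form together, the correlations for numbers 1 to 7 were 0.02, -0.09, -0.05, 0.28, -0.15, 0.06 and -0.11. The replicate block without the name form called 5466 genes.

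In the libraries without the GC prefix, signs reversed for the list means of PPAR targets (-0.0089), stem cell genes (0.19), absorptive colonocyte markers (-0.27) and T and NK cell markers (0.060), and for Itgb2 (0.0046), Msn (0.19), Ftl1 (-0.037), Slc12a2 (0.060), Krt20 (-0.019), Guca2a (-0.19), Itgae (0.082), Ighm (0.41) and Cd37 (0.42). With the non-epithelial marker score, which holds Fcer1g and Cd37 themselves, they reversed for Ifng (0.13), Fcer1g (0.16) and Cd37 (0.13). Signs also reversed in female libraries for Ptges (-0.048) and with the replicate block for Dusp1 (0.18). The cause was not tested. Of these, the stem cell and absorptive lists passed by camera in the reversed direction, where exact permutation gave p of 0.2 and 0.0667. Over 176 genes and 19 settings, 527 values lost a call, 46 gained one and 14 reversed; over 31 lists and 17 settings the numbers were 18, 29 and 4. Changes of sign in values called under neither setting were not counted as reversals; with single-library omissions included these numbered 119 for genes and 97 for lists. Gpx4 lost its call without the GC prefix (0.07), in male libraries (0.17) and with the marker score (0.34), and Reg3g under 7 settings (1.75 to 5.24). The call was lost with its direction kept under 8 settings for Reg3b, 7 for Fcer1g, 6 for Klk15 and Sox9, 5 for Retnlb, Cd3d and Cd3e, 4 for Dusp1 and Slc12a2, and 3 for Egr2 and Aldh1a7. Depths of 13996288 to 19512755 counts left 14321 of 54392 genes testable.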

Other observations

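The gene families and values in this part were chosen after the data were seen, and no explanation of them was tested. Ribosomal protein genes lay higher with fish oil/pectin, 81 of 90 passing upward and 2 downward, with a median log2 fold change of 0.48 (0.65 in GC-named and 0.13 in the other libraries). Mitochondrial ribosomal protein genes had 74 of 77 higher (median 0.44) and proteasome subunits 38 of 38 higher (median 0.43). With the transcript length trend removed these medians were 0.28, 0.29 and 0.33, and scaled by total counts they were 0.40, 0.36 and 0.35. Of 14 collagen genes 3 fell and 0 rose (median -0.35, or -0.22 with the length trend removed). Of the 3 epithelial sodium channel subunits 2 fell, with a median of -0.65, or -0.79 with the length trend removed.

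Fish oil/pectin library 7 had 0.631 CPM of Hoxd13, a distal colon gene, against 23.9 to 101 CPM in the other 15 libraries, and 1765 CPM of Fabp6. Without that library Fabp6 still differed between the diets (log2 fold change 1.46 ± 0.27, edgeR adjusted p = 0.00135).

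By Y-linked counts all 6 libraries without the GC prefix were male, as were corn oil/cellulose libraries 5 and 9 and fish oil/pectin library 3 among the GC-named, so the name forms differ in sex as well as in whatever the names mark.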
